A study of Mus musculus with 11 samples.

How the data were processed

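The data are single-nucleus RNA sequencing libraries (10x 3' chemistry, v3.1) of individual mouse pituitaries, 1 mouse per library. The authors deposited filtered matrices of raw UMI counts per gene and barcode, made with Cell Ranger 7.1.0 against mm10 per the submitters' processing notes. The annotation release, the intron setting and the floxed exons are not given in the sources used here. The files hold 32285 genes, of which 32235 (99.85%) were placed on the genome by their identifiers in a GENCODE annotation of the same build. The values were checked to be whole numbers, and libraries of 1 group were checked for being copies of each other (the smallest chi-square per degree of freedom within a group was 3.86). Matrices of 7 of the 11 samples were used and the other 4 were not analysed here.

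Nuclei with at least 500 genes and at most 5% mitochondrial UMIs were kept. Scrublet scores (in scanpy 1.11.5, with anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, scikit-image 0.26.0 and Python 3.11.15) were used to remove the highest-scoring 0.8% per 1000 nuclei of each library, since the automatic threshold marked 1 nucleus in Alk4 cKO 1 and in Alk5 cKO 2. This rule expected 1392, 492, 875, 286, 463, 1200 and 2473 nuclei, and nuclei with the same score as the last of these (146, 45, 64, 58, 120, 74 and 92) were all removed. In all 1396, 522, 908, 332, 501, 1221 and 2482 nuclei were removed from Alk4 cKO 1 and 3, the Alk4 control, Alk5 cKO 1, 2 and 3 and the Alk5 control. All libraries were clustered together without integration (3000 variable genes, 40 principal components, 15 neighbours, Leiden resolution 1.0 in igraph 0.11.9), leaving out Fshb, Acvr1b, Tgfbr1, Xist, Y-linked and mitochondrial genes. A cluster was named when at least 3 markers of a class reached 10 CPM and a fold of 2 over the 25th percentile of clusters, with a log2 gap of 1 to the next class and at most 50% predicted doublets. There were 28 clusters, not all of which could be named. Gonadotropes lay mostly in 1 cluster in females and in another in males, 3515 nuclei in all. Because Gnrhr and other genes that define the cluster differed between genotypes, clustering was repeated without the gonadotrope list and the 137 genes called between genotypes, and 98.18% of the gonadotropes were found again.

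UMI counts were summed per library over the nuclei of each class and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, robust, TMM scaling, filterByExpr with a minimum count of 10; 14349 genes in gonadotropes; common biological coefficient of variation 0.222, median prior degrees of freedom 9.17). The groups are Alk4 cKO (2 libraries), Alk4 control (1), Alk5 cKO (3) and Alk5 control (1). A fit of the 4 group means (3 residual degrees of freedom) gave the effect in each line, the difference between the effects and the contrast between lines, so that a single control takes its spread from the other groups. An additive fit of line and genotype (4 residual degrees of freedom) gave the common effect. Genotype effects in gonadotropes were compared with those in somatotropes by an interaction with library as a block. Adjusted p are Benjamini-Hochberg values over the genes of 1 contrast, called under 0.05. Log2 fold changes are from the model, and CPM are counts scaled to the library total with TMM factors. DESeq2 1.42.0 was the other tool.

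The 17 gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and at an estimated correlation, and with fry, on voom-transformed sums. They are gonadotrope identity and hormones, TGF-beta family receptors and ligand traps, TGF-beta family ligands and inhibin subunits, SMADs and cofactors, canonical SMAD2/3 targets, canonical BMP targets, immediate early genes, GnRH signalling, steroid hormone receptors, regulated secretion, ER stress, voltage-gated channels, cell adhesion and axon guidance, hormone transcripts of other pituitary cells, markers of non-endocrine pituitary cells, mitochondrial transcripts and heat shock. List members not tested, such as Fst, Fstl3, Mstn, Bmp2, Bmp4, Esr2, Hspa1a and Ptprc, had too few counts.

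Shares of nuclei carry exact (Clopper-Pearson) 95% intervals and were compared by exact two-sided permutation of genotype within line, which has 12 arrangements. For shares with an Fshb or Lhb UMI, nuclei were thinned to 1000 UMIs and shallower ones left out, and a count of 0 is given with its bound or as 3 counts of the total. These intervals and bounds cover counting error only.

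The comparisons, the tests, the gene lists, the markers, most alternatives and the rule for named genes were chosen before the data were examined. Named always are Fshb, Lhb, Cga, Gnrhr, Nr5a1, Foxl2, Acvr1b, Tgfbr1, Inha, Inhbb, Fst and Smad7. In each line and in the common effect the 8 higher and the 8 lower genes with the largest fold change are named that passed, lay on 1 side in every cKO library, had a mean of at least 20 CPM and a symbol that is not a clone, a pseudogene, a Y-linked gene or Xist; where under 5 passed, genes of smallest p fill up to 5 as values only, and the difference takes 4 each way. List members that passed are named, otherwise those of smallest p.

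Alternatives were RLE scaling, DESeq2, no filter on low counts, a mean count of at least 50, no robust fit, only the libraries of the line, sums thinned to the smallest total, at least 1000 genes per nucleus, doublets kept, clustering each library alone (resolution 0.8), clustering without the gonadotrope list, leaving out each cKO library in turn (in the common effect also each control), and, for shares, no thinning or 2000 UMIs. Chosen after the data were seen were leaving out Alk4 cKO 1 and Alk5 cKO 2 together, counting only nuclei of named clusters, and the clustering without the called genes.

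The pipeline was tested on simulated data with 1 control per line (13986 genes tested): edgeR recovered 4.62%, 59.0% and 90.6% of genes changed by 1, 2 and 4 log2 units in the Alk4 line, 4.62%, 67.2% and 89.1% in the Alk5 line and 35.4%, 90.2% and 96.9% in the common effect, with 11 of 108, 12 of 113 and 11 of 151 calls false. The interaction recovered 31.1%, 32.8% and 75.4% of genes changed by 2 log2 units, and a test of the difference with none simulated made 2 calls. A shifted list was found by camera in all 3 comparisons, also at an estimated correlation (unadjusted p 0.00307, 0.00349 and 0.000371). The simulated genes were drawn independently, so this does not test lists whose members move together.

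Some named genes share bases with another annotated gene, and whether the counting used strand is not given in the sources used here. On the same strand these are Elmo1, Ptpro, Grin3a, Pcdh15, Hs6st3 and Pld5. On the opposite strand these include Cntn5, Prmt8, Lncbate1 (which lies in Zfhx3), Lhb, Cga, Nnat, Prkg1, Dgkb, Nrp2, Kirrel3 and Rftn1. Classes with under 50 nuclei in any library (endothelial, pericyte, macrophage and others) were not tested.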

Results

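Nuclei from individual frozen mouse pituitaries were profiled by single-nucleus RNA sequencing, in a study of how myostatin acts on the synthesis of FSH, the hormone made by gonadotropes. In one line the activin type I receptor gene Acvr1b (which encodes ALK4) was removed in gonadotropes of females aged 12 to 13 weeks, and in the other Tgfbr1 (which encodes ALK5) was removed in gonadotropes of males aged 8 to 9 weeks. The removal was by Cre recombinase carried at the Gnrhr locus, and the controls had the floxed gene without Cre. Each library came from 1 mouse. Of 11 samples, 7 are used: Alk4 cKO females 1 and 3, Alk4 control female 3, Alk5 cKO males 1, 2 and 3, and Alk5 control male 1. The other 4 were not analysed here, so each line is compared with 1 control library.

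The deposited UMI counts totalled 65849493 in Alk4 cKO 1, 45833254 in Alk4 cKO 3, 47557020 in the Alk4 control, 30234300 in Alk5 cKO 1, 15151506 in Alk5 cKO 2, 27524375 in Alk5 cKO 3 and 38344120 in the Alk5 control. In the same order, 13189, 7838, 10454, 5976, 7602, 12245 and 17579 nuclei were kept, with medians of 4544, 5182, 3937, 3916, 902, 1849 and 1813 UMIs per nucleus. Alk5 cKO 2 stood apart by depth, since 15687 of its 23289 barcodes had under 500 genes. After predicted doublets were removed, gonadotropes, recognised by Lhb, Gnrhr, Nr5a1, Tgfbr3l and Foxp2, numbered 288, 234, 366, 312, 801, 766 and 748. Their summed counts ranged from 836419 to 2291750 UMIs per library. Alk4 cKO 1 stood apart by state: 44.7% of its nuclei lay in clusters that could not be named, against 0.164% to 14.8% in the other libraries. Most of them lay in a cluster led by the immediate early genes Fos, Dusp1 and Junb. In the clustering without the gonadotrope list and the called genes, such a cluster (5209 nuclei) went unnamed because it had markers of both melanotropes and gonadotropes. Whether gonadotropes of Alk4 cKO 1 lay there, outside its sums and its share, was not tested.

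Transcripts of the floxed genes did not differ detectably in gonadotropes. Acvr1b (ENSMUSG00000000532) stood at 47.9 and 32.7 CPM (counts scaled to the library total) in Alk4 cKO 1 and 3 against 28.5 in the control, a log2 fold change of 0.49 (SE 0.41, adjusted p = 1 by edgeR). Tgfbr1 (ENSMUSG00000007613) stood at 77.8, 59.4 and 51.5 CPM in Alk5 cKO 1, 2 and 3 against 81.3 in the control, a log2 fold change of −0.37 (SE 0.28, adjusted p = 0.905 by edgeR). Tags of a 3' assay can lie outside the deleted exons, which are not given in the sources used here, so these values check neither the deletion nor the labels.

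The comparison of Alk5 cKO with control males asks which gonadotrope transcripts depend on ALK5. Cntn5, which encodes the neural adhesion protein contactin 5 (ENSMUSG00000039488, chromosome 9, 9660891 to 10904775, mm10), fell 63.5-fold, from 809 CPM in the control to 11.7, 17.5 and 10.7 in the 3 cKO libraries (log2 fold change −5.99, SE 0.28, adjusted p = 8.90e-07). The phospholipid phosphatase gene Plpp4 fell 20.1-fold (log2 −4.33, SE 0.41, adjusted p = 0.00114) and the arginine methyltransferase gene Prmt8 fell 14.9-fold (log2 −3.89, SE 0.43, adjusted p = 0.00355). Gata2, a transcription factor of gonadotrope and thyrotrope differentiation, fell from 211 CPM to 60.5, 87.4 and 66.5 (log2 −1.58, SE 0.26, adjusted p = 0.0252). Gnrhr, the receptor for GnRH, fell from 1305 CPM to 609, 530 and 365 (log2 −1.38, SE 0.27, adjusted p = 0.0426). Car10, a carbonic anhydrase-related gene, rose 9.50-fold (log2 3.25, SE 0.39, adjusted p = 0.00355).

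In all, 28 genes rose and 81 fell among 14349 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and all 109 lay on the same side of the control in each of the 3 cKO libraries. DESeq2 called 145, of which 81 were shared, and gave no adjusted p for 3895 genes. The other named genes that rose were Lncbate1, a long noncoding RNA (log2 4.28), the protocadherin gene Pcdh15 (2.68), the heparan sulfate sulfotransferase gene Hs6st3 (2.58), the diacylglycerol kinase gene Dgkb (2.52), Itgbl1 (2.50), the kinase gene Nek10 (2.37) and the receptor phosphatase gene Ptprz1 (2.37). Those that fell were Thsd7b (log2 −3.68), the endopeptidase gene Phex (−3.51), the cGMP-dependent kinase gene Prkg1 (−3.44), the neuronal membrane protein gene Sez6 (−3.32) and the lipid raft gene Rftn1 (−3.10). The 1 control library is assumed to vary like the other groups. The count was 16, 13 and 21 without Alk5 cKO 1, 2 and 3, 403 and 423 without Alk4 cKO 1 and 3 (which share the spread), and 298 without both Alk4 cKO 1 and Alk5 cKO 2. Among the named genes, Cntn5, Plpp4, Prmt8, Sez6, Prkg1, Dgkb and Hs6st3 passed under every alternative run. Without any 1 of the 3 Alk5 cKO libraries Gata2 (adjusted p 0.122, 0.0719 and 0.0849 without 1, 2 and 3), Gnrhr (0.122, 0.186 and 0.118), Itgbl1, Nek10, Pcdh15, Phex and Thsd7b (0.0798 to 0.236) did not pass. Ptprz1 and Rftn1 did not pass without Alk5 cKO 1 or 2 (0.0638 to 0.124), nor Lncbate1 without Alk5 cKO 2 (0.0719).

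**Figure D1:**
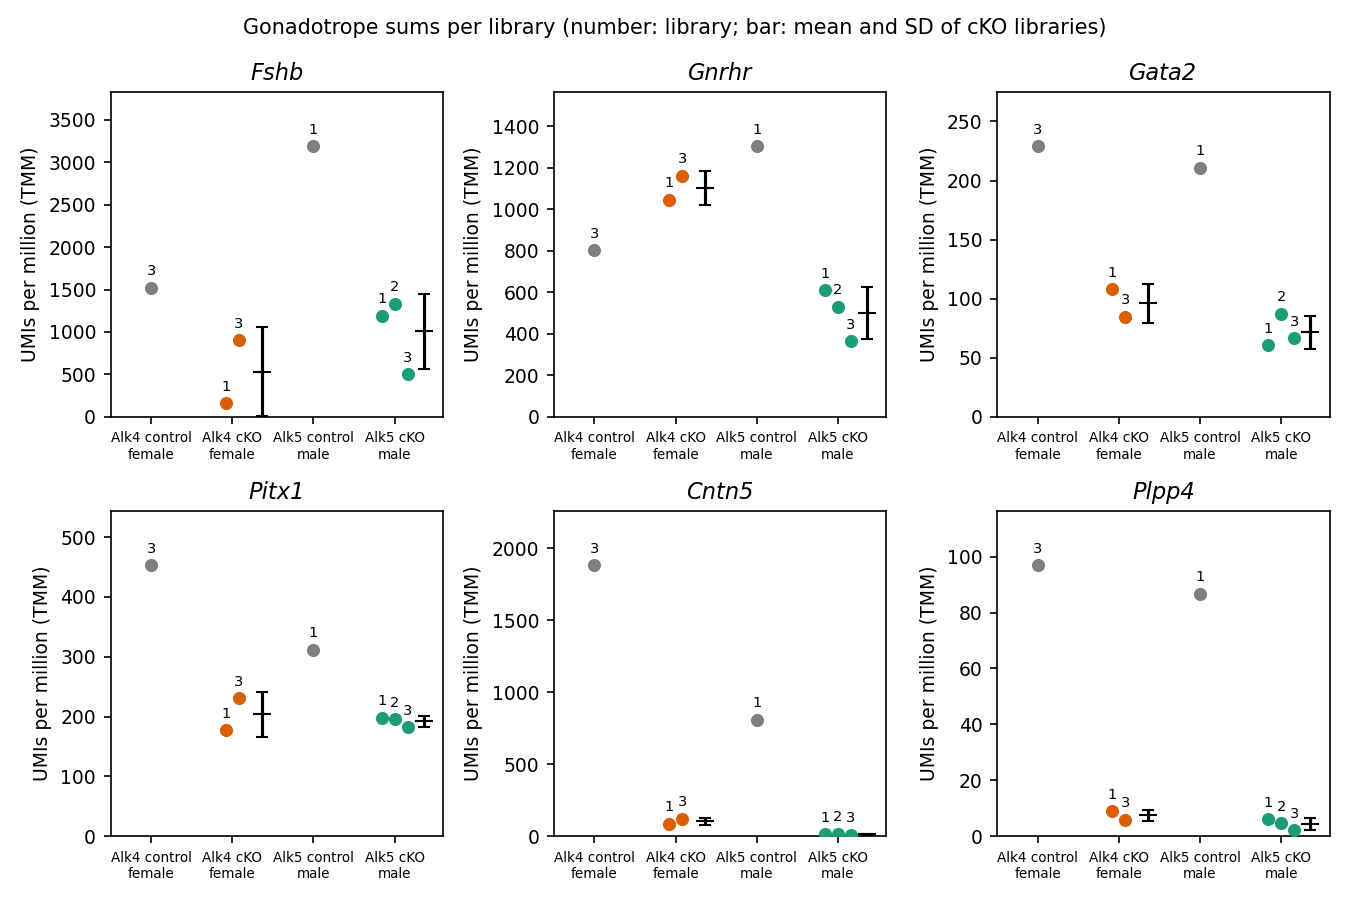
Level of the named genes in gonadotropes of each library, in CPM on an axis from 0, with the number of the library above each point and the mean and SD of the cKO libraries as bars. Cntn5 lies at 84.2 and 120 in the Alk4 cKO libraries against 1882 in their control, and at 10.7 to 17.5 in the Alk5 cKO libraries against 809.

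Among the lists fixed beforehand, the gonadotrope identity and hormone list had 2 members that fell in Alk5 cKO, Gata2 and Gnrhr, none that rose, and 15 tested (2 adjusted over the list alone). Gnrhr is also the only member of the GnRH signalling list to fall (1 of 17 tested; 1 adjusted over the list alone). In the other 15 lists no member passed over all genes. Members that passed only when adjusted over the list alone included the type I receptor gene Bmpr1b (log2 −1.97), the inhibin beta B gene Inhbb (−2.05, over all genes adjusted p = 0.0845), the signal transducer gene Smad3 (−1.56, over all genes adjusted p = 0.0554) and the BMP antagonist gene Grem1 (−4.32). So did the secretion genes Syt1 (1.41) and Rab3b (−0.77), the channel genes Cacna1c (−1.50) and Kcnma1 (−0.95), and the adhesion and guidance genes Nlgn1 (−1.54) and Unc5d (1.66). That is 1, 1, 1, 1, 2, 2 and 2 members of their 7 lists adjusted over the list alone. As a set, mitochondrial transcripts were lower (median log2 −0.53, 10 members, none passing alone, camera adjusted p = 0.00354; adjusted p = 0.457 with an estimated correlation). The median percent of mitochondrial UMIs over nuclei of all classes was 0.169, 0.0820 and 0.259 in Alk5 cKO 1, 2 and 3 against 0.208 in the control. The other 16 lists had camera adjusted p from 0.126 to 0.856. Over all genes Inhbb, Smad3, Syt1, Cacna1c, Kcnma1, Nlgn1, Unc5d, Egr1 (log2 −2.08 with all libraries) and Nr3c2 (1.48) passed without either Alk4 cKO library (adjusted p 0.000145 to 0.0289). So did Bmpr1b (0.0498) and mt-Nd4 (0.0482) without Alk4 cKO 3 and Grem1 without Alk5 cKO 3 (0.00261). The canonical SMAD2/3 target list had a median log2 of −0.41 with camera adjusted p = 0.141, and the adhesion list's positive median (0.15), mean (0.33) and camera direction differ in sign from its fry direction.

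The comparison of Alk4 cKO with control females asks the same of ALK4. Cntn5 fell 18.7-fold, from 1882 CPM in the control to 84.2 and 120 in cKO 1 and 3 (log2 fold change −4.22, SE 0.29, adjusted p = 6.57e-05). Plpp4 fell 13.1-fold (log2 −3.71, SE 0.41, adjusted p = 0.00712), from 96.9 CPM to 8.84 and 5.89, and Prmt8 fell 11.3-fold (log2 −3.49, SE 0.45, adjusted p = 0.0230), from 66.6 CPM to 8.38 and 3.21. These were the 3 genes that passed (0 rose, 3 fell; edgeR, 14349 genes, 639 at an unadjusted p under 0.05), each lower in 2 of 2 cKO libraries. DESeq2 called 9, these 3 among them. Genes of smallest p that did not pass were Chl1, a neural adhesion gene (log2 2.50, adjusted p = 0.123), Elmo1 (1.73), Grin3a (1.97), Car10 (1.43), Ptpro (1.18), Sez6 (−2.48, adjusted p = 0.0708) and Kirrel3 (−1.70, adjusted p = 0.0708). The count was 75 without Alk4 cKO 1, 84 without Alk4 cKO 3, 1 without Alk5 cKO 2 and 28 without both Alk4 cKO 1 and Alk5 cKO 2. Cntn5 passed in 17 of 18 alternatives (adjusted p = 0.0831 with at least 1000 genes per nucleus) and Plpp4 in 16 (0.111 without Alk5 cKO 2, 0.0750 with thinned sums). Prmt8 passed in 12 of 17 (0.0752 and 0.217 without Alk5 cKO 1 and 2, 0.0524 without the robust fit, 0.165 with thinned sums, 0.336 with only the libraries of the line). Without Alk4 cKO 1 or 3 the Alk4 line is 1 library against 1, so the counts there rest on no spread between females. The log2 fold changes without Alk4 cKO 1 and 3 were 2.89 and 1.99 for Chl1, −2.88 and −2.18 for Sez6 and −1.68 and −1.71 for Kirrel3. Without Alk4 cKO 3 they were 2.03 for Elmo1 and 2.60 for Lhb.

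No list member passed over all genes in the Alk4 comparison, and no list passed by camera (adjusted p 0.0732 to 0.979 over the 17 lists) or fry (adjusted p 0.849 to 0.974). Adjusted over the list alone, 2 of 15 gonadotrope identity members passed, Gata2 (108 and 84.6 CPM against 229; log2 −1.26, SE 0.28, over all genes adjusted p = 0.332) and Pitx1, a homeobox gene of pituitary development (177 and 230 CPM against 453; log2 −1.17, SE 0.24, over all genes adjusted p = 0.292). So did 1 of 11 channel genes, Kcnh1 (log2 −3.11, over all genes adjusted p = 0.447). The immediate early list had a median log2 of 1.89 (camera adjusted p = 0.0803). This went with Alk4 cKO 1, where Egr1 stood at 255 CPM against 9.64 in Alk4 cKO 3 and 27.2 in the control. The identity list's median (−0.11) and camera direction were negative and its mean (0.01) positive. The list of other pituitary hormones likewise had a negative median (−0.03) and camera direction and a positive mean (0.01). The SMAD2/3 target list (median 0.31, mean 0.34) and the BMP target list (0.22, 0.29) had positive medians with a negative camera direction, and the secretion list a median of 0.04 with a negative camera direction. Without Alk4 cKO 1, which leaves 1 library against 1, the log2 fold change was −1.46 for Gata2 and −4.18 for Kcnh1. Without Alk4 cKO 3, likewise, it was −1.36 for Pitx1, 3.51 for Acvr1c and 2.60 for Nr4a1.

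Taking both lines together, with line as a term, asks what distinguished cKO from control gonadotropes whichever receptor was removed. Cntn5 fell 35.3-fold (log2 fold change −5.14, SE 0.35, adjusted p = 0.000747), Plpp4 16.1-fold (log2 −4.01, SE 0.29, adjusted p = 9.55e-05), and Prmt8 13.0-fold (log2 −3.70, SE 0.30, adjusted p = 0.000211). Sez6 fell 7.43-fold (log2 −2.89, SE 0.27, adjusted p = 0.000747) and the semaphorin co-receptor gene Nrp2 6.37-fold (log2 −2.67, SE 0.26, adjusted p = 0.000747). The transcription factors Gata2 (log2 −1.43, SE 0.19, adjusted p = 0.00756) and Pitx1 (log2 −0.93, SE 0.17, adjusted p = 0.0436) fell. Genes that rose included the adhesion genes Pcdh15 (log2 2.25) and Chl1 (1.80), the phospholipase D family gene Pld5 (2.20), Itgbl1 (2.06), Ptprz1 (1.81), Elmo1 (1.66), the kinase gene Hunk (1.66) and the imprinted gene Nnat (1.63). Phex (−2.85), Rftn1 (−2.75) and Nkain3 (−2.23) fell.

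The common effect covered 73 genes, 20 that rose and 53 that fell (edgeR with line as an additive term, 14349 genes), each on the same side of its control in all 5 cKO libraries. Of these, 45 were among the 109 of the Alk5 comparison and 3 among the 3 of the Alk4 comparison. DESeq2 called 152, of which 71 were shared. The count was 314 without Alk4 cKO 3, 22, 17 and 41 without Alk5 cKO 1, 2 and 3, 3 without the Alk5 control, and 12 without both Alk4 cKO 1 and Alk5 cKO 2. Without the control of a line the genotype term comes from the other line alone, so those fits do not test an effect common to both. Cntn5, Plpp4 and Prmt8 passed under every alternative run. Gata2 (adjusted p = 0.332), Sez6 (0.0881), Nrp2 (0.194) and the other named genes of this comparison (0.124 to 0.956) did not pass without the Alk5 control. Pitx1 passed in 8 of 19 alternatives (not without Alk4 cKO 1, the Alk4 control, any Alk5 cKO library or the Alk5 control, with adjusted p from 0.0845 to 0.307, nor under 5 other settings, 0.0543 to 0.244). Nkain3 did not pass without Alk5 cKO 2 either (0.0528), nor Elmo1 without Alk5 cKO 1 (0.0518) or the Alk4 control (0.0547), nor Rftn1 without Alk5 cKO 1 (0.0656) or 2 (0.0960). Pcdh15, Phex, Itgbl1, Ptprz1, Pld5, Hunk, Nnat and Chl1 did not pass without any 1 of the 3 Alk5 cKO libraries (0.0538 to 0.173), nor the last 4 of these without the Alk4 control (0.0547 or above).

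**Figure D2:**
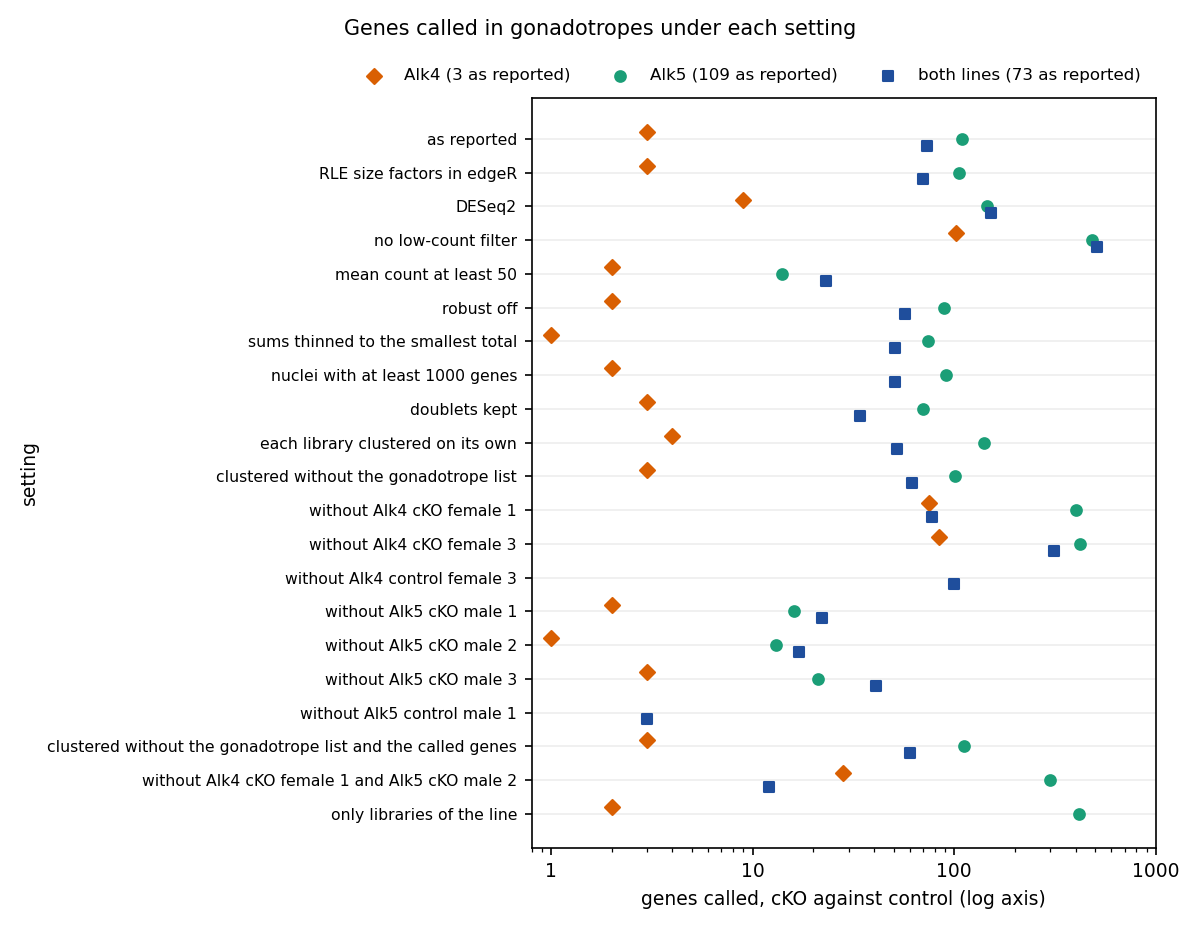
Number of genes called in gonadotropes under each processing setting (vertical axis), on a log axis, for the Alk4 line, the Alk5 line and both lines together. Counts as reported are 3, 109 and 73, and they range from 1 to 102, 13 to 485 and 3 to 514 over the settings.

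Of the lists, gonadotrope identity fell as a set (2 of 15 members fell, Gata2 and Pitx1; 2 adjusted over the list alone; camera adjusted p = 0.0438; adjusted p = 0.397 with an estimated correlation; fry adjusted p = 0.105 for 1 direction and 0.00104 for change in either direction). Steroid hormone receptors rose as a set with no member passing over all genes (camera adjusted p = 0.0160; adjusted p = 0.397 with an estimated correlation). The progesterone receptor gene Pgr (log2 0.65) passed when adjusted over the list alone. Mitochondrial transcripts fell as a set (median log2 −0.45, none of 10 passing alone; camera adjusted p = 0.00160; adjusted p = 0.821 with an estimated correlation). The other 14 lists had camera adjusted p from 0.190 to 0.993, with no member passing over all genes. Adjusted over the list alone, Inhbb (log2 −1.67), Smad7 (−0.76, in both the SMAD and the SMAD2/3 target list), Id4 (1.59) and Grem1 (−3.81) of the BMP targets, Syt1 (1.02) and Rab3b (−0.60) of secretion, and Rbpms (0.75), a stem cell marker, passed. Without Alk4 cKO 1, which leaves 1 Alk4 cKO library, the log2 fold change was −1.90 for Inhbb. Without Alk4 cKO 3, likewise, it was 1.19 for Syt1, 0.88 for Rbpms, 2.13 for Acvr1c and 0.84 for Kcnb2. Gnrhr had −0.64 with all libraries and −1.38 without the Alk4 control, where the genotype term comes from the Alk5 line alone. Receptors and ligand traps (median −0.06, mean 0.05), SMAD2/3 targets (−0.04, 0.09), BMP targets (0.41, −0.11) and secretion (0.11, 0.04) had a median or mean opposed in sign to the other or to the negative camera direction.

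The hormone genes themselves did not pass. Fshb, the beta subunit of FSH (ENSMUSG00000027120, chromosome 2, 107056140 to 107059656), stood at 159 and 904 CPM in Alk4 cKO 1 and 3 against 1522 in the control, and at 1190, 1332 and 504 CPM in Alk5 cKO 1, 2 and 3 against 3189. Its log2 fold change was −1.55 (SE 1.15, adjusted p = 1) in the Alk4 line, −1.66 (SE 1.04, adjusted p = 0.876) in the Alk5 line and −1.61 (SE 0.65, adjusted p = 0.682) in both, with all 5 cKO libraries below their control (edgeR). Cga, the shared alpha subunit, had 0.83 and 0.58, and its libraries went opposite ways: 32411 and 6882 CPM in Alk4 cKO 1 and 3 against 11030, and 19003, 34298 and 12293 in Alk5 cKO 1, 2 and 3 against 14647. Lhb, the beta subunit of LH, had 1.93 and −0.04, from 12 to 72 UMIs per library, with 33.5 and 8.03 CPM in Alk4 cKO 1 and 3 against 5.43, so that the Alk4 value rests mostly on cKO 1. Log2 fold changes in the Alk4 and Alk5 lines were −1.12 and −2.05 for Inhbb, −0.47 and −0.28 for the inhibin alpha gene Inha, −0.86 and −0.67 for the inhibitory SMAD gene Smad7, −0.54 and −0.31 for Foxl2 and 0.14 and 0.16 for Nr5a1, none of which passed. The activin-binding protein gene Fst had 0 to 2 UMIs per library and Mstn, the gene of myostatin, had 0 in every library, where a count of 0 allows up to 1.31 to 3.59 CPM.

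Per nucleus, the share of gonadotropes with an Fshb UMI was lower in every cKO library than in its control. With each nucleus thinned to 1000 UMIs it was 5.59% (exact 95% interval 3.23 to 8.93, 286 nuclei) and 38.5% (32.2 to 45.0, 234) in Alk4 cKO 1 and 3 against 63.4% (58.2 to 68.3, 366) in the control. It was 39.3% (33.7 to 45.0, 303), 52.3% (46.7 to 57.9, 323) and 21.4% (18.5 to 24.5, 734) in Alk5 cKO 1, 2 and 3 against 87.7% (85.1 to 90.0, 739). The mean cKO share was −41.4 percentage points from control in the Alk4 line and −50.0 in the Alk5 line. An exact two-sided permutation test of genotype within line gave p = 0.0833, the smallest its 12 arrangements allow, so the design cannot reach 0.05. Unthinned or thinned to 2000 UMIs p was 0.167 by the same exact test. In Alk5 cKO 2, 478 of 801 gonadotropes had under 1000 UMIs and were left out. In somatotropes, which should lack Fshb, the share was 0.879%, 2.41% and 5.80% in the Alk4 line and 4.62%, 3.69%, 3.79% and 24.7% in the Alk5 line, in the same order of libraries, so background also was highest in each control. Median depths before thinning were 5314 to 7684 UMIs in gonadotropes and 3511 to 4931 in somatotropes of 4 libraries, and 924 to 2379 and 876 to 1769 in Alk5 cKO 2, Alk5 cKO 3 and the Alk5 control. Lhb UMIs were found in 0.427% to 3.15% of gonadotropes and 0 to 0.347% of somatotropes at 1000 UMIs, where 0 of 949 nuclei in Alk5 cKO 2 has an exact upper bound of 0.388%.

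**Figure D3:**
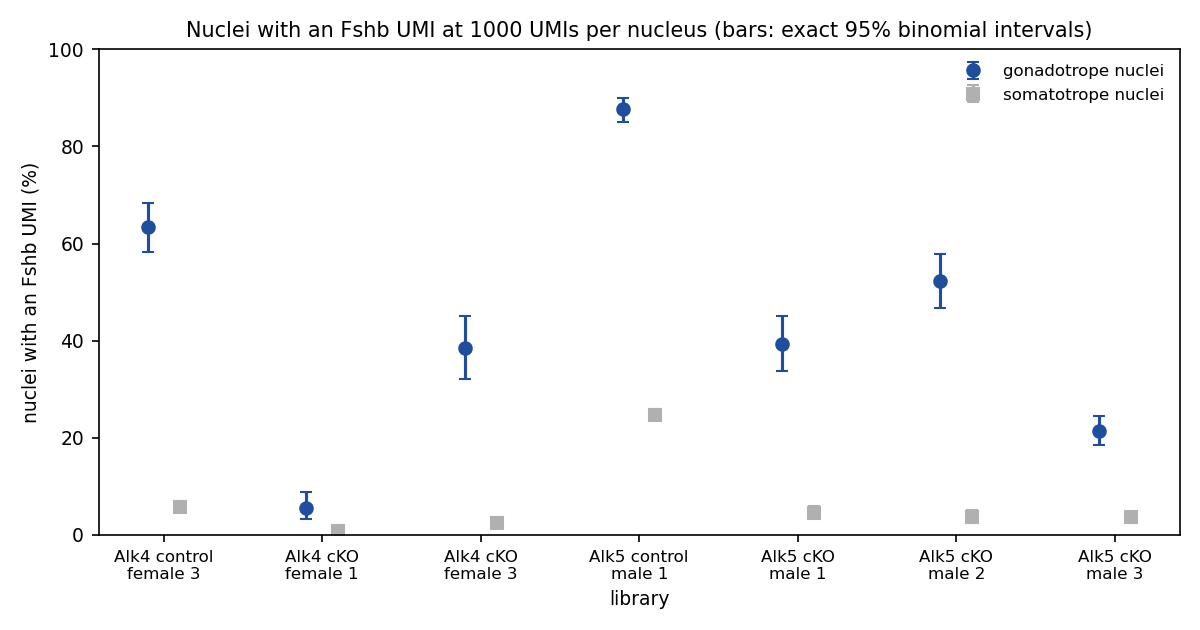
Percent of gonadotropes and of somatotropes with at least 1 Fshb UMI in each library, every nucleus thinned to 1000 UMIs, with exact 95% binomial intervals as bars. The controls lie at 63.4% and 87.7% of gonadotropes and the cKO libraries between 5.59% and 52.3%, with somatotropes at 0.879% to 24.7%.

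The effects in the 2 lines were then compared gene by gene. Of the 109 genes called in Alk5 cKO, 92 (84.4%) had the same sign in Alk4 cKO, against 52.0% of the 14240 genes called in neither line. The 3 genes that fell in the Alk4 line all fell in the Alk5 line, where 0.0169 would be shared by independent choice. These are counts across genes, which are not independent replicates. In the test of the difference itself no gene passed (edgeR, 0 of 14349, 678 at an unadjusted p under 0.05; DESeq2 2). Genes of smallest p, Gtf2f2 (log2 difference 2.01), Lrp1b (2.04), Ankrd55 (2.29), Fhod3 (1.55), Dgkb (−2.09), Hs6st3 (−2.09), Lncbate1 (−4.40) and Aox1 (−2.85), all had an adjusted p of 0.690, as did Gnrhr (1.82, SE 0.43). Without Alk4 cKO 1 the count was 125 and Gnrhr (adjusted p = 0.0365), Gtf2f2, Lrp1b, Ankrd55, Dgkb, Hs6st3 and Lncbate1 (0.00224 to 0.0365) passed. It was 6, with Dgkb (0.0463), without Alk4 cKO 3, and 46 without both Alk4 cKO 1 and Alk5 cKO 2. Line, sex, age and strain go together, so a difference between the effects cannot be assigned to the receptor.

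Camera placed 4 lists above the other genes in the difference of the Alk4 from the Alk5 effect, none with a member passing over all genes: GnRH signalling (adjusted p = 0.00767), immediate early genes (0.0134), receptors and ligand traps (0.0208) and heat shock genes (0.0208). With an estimated correlation the adjusted p were 0.550, 0.860, 0.550 and 0.550, and fry's 0.567, 0.926, 0.567 and 0.567. The other 13 lists had camera adjusted p from 0.0884 to 0.860. Adjusted over the list alone, Gnrhr passed in the identity and in the GnRH signalling list, and so did Smad3, Cacna1c (log2 difference 1.75) and Kcnma1 (1.35). Without Alk4 cKO 1, which leaves 1 Alk4 library against 1, the log2 difference was 2.36 for Smad3 and 2.15 for Cacna1c. It was −2.35 for Nr3c2, −1.77 for Cadps and 1.88 for Gnrhr. Medians and means of opposite sign were found for the identity (−0.02, 0.41), ligand (−0.06, 0.03), BMP target (−0.67, 0.07), steroid receptor (−0.11, 0.28), ER stress (−0.03, 0.02) and adhesion (−0.03, 0.18) lists.

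**Figure D4:**
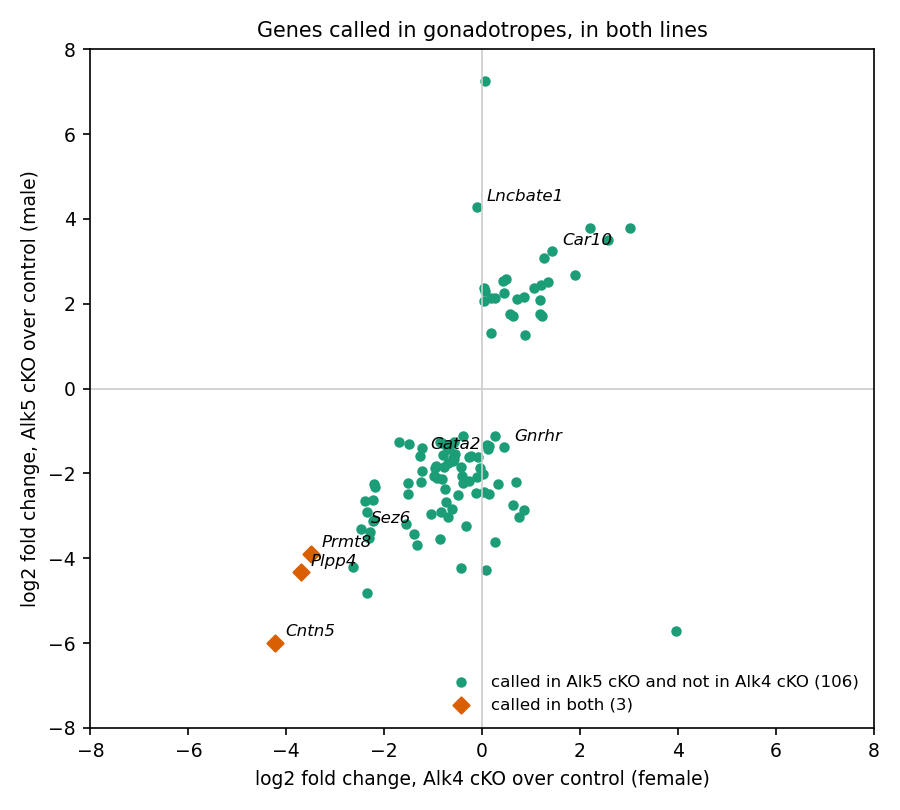
Log2 fold change of cKO against control in gonadotropes of the Alk5 line against that of the Alk4 line, 1 point per gene called in the Alk5 line, with the 3 genes called in both lines as diamonds. Cntn5 lies at −4.22 and −5.99, and 92 of the 109 genes called in the Alk5 line have the same sign in both.

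Somatotropes of the same libraries, where the Gnrhr Cre is not active, served as the reference for changes of a whole library. Cntn5 had a log2 fold change of −0.11 in somatotropes of the Alk4 line and −0.31 in the Alk5 line, and Plpp4 −0.06 and 0.86. Both were scarce there, at 0.343 to 2.17 CPM (Cntn5) and 6.65 to 14.0 CPM (Plpp4). Gnrhr had −1.86 (SE 0.66) in somatotropes of the Alk5 line, no smaller than in gonadotropes (gonadotrope minus somatotrope effect 0.55, adjusted p = 0.861 by edgeR). It stood there at 4.76, 4.81 and 1.79 CPM in Alk5 cKO 1, 2 and 3 against 13.7 in the control, which may be background. Fshb had −1.81 and −2.58 in somatotropes of the Alk4 and Alk5 lines (0.02 and 0.83 relative to them), and Prkg1 −1.50 in the Alk5 line. Somatotropes should lack Fshb, so its counts there may be background that follows Fshb of gonadotropes. The relative values of Fshb therefore cannot tell whether its fall was limited to gonadotropes. Of the called genes with a value in somatotropes, 0 of 2 in the Alk4 line, 9 of 96 in the Alk5 line and 2 of 66 in both together had a log2 fold change there of the same sign and at least 0.5 times that in gonadotropes. The test of the gonadotrope against the somatotrope effect (edgeR, library as a block, 14349 genes) called 1 gene in the Alk4 line, Plpp4 (log2 −3.68, adjusted p = 0.0200). It called 54 in the Alk5 line (26 higher, 28 lower), among them Plpp4, Cntn5, Car10, Hs6st3, Dgkb, Sez6 and Itgbl1, and 29 in both lines together (14 higher, 15 lower), among them Plpp4, Cntn5, Sez6, Hunk, Chl1, Nnat and Itgbl1. Of the 3, 109 and 73 genes of the gonadotrope comparisons, 1, 24 and 16 passed relative to somatotropes. The counts changed without single libraries: 9, 16 and 0 in the Alk4 line without Alk4 cKO 1, Alk4 cKO 3 and Alk5 cKO 2; 189, 200, 23, 2 and 15 in the Alk5 line without Alk4 cKO 1 and 3 and Alk5 cKO 1, 2 and 3; and 80, 222 and 5 in both lines without Alk4 cKO 1, Alk4 cKO 3 and Alk5 cKO 2. Without both Alk4 cKO 1 and Alk5 cKO 2 they were 86, 354 and 213.

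In the other classes with at least 50 nuclei in each library (somatotropes, lactotropes, melanotropes, corticotropes, thyrotropes and stem cells), few genes passed. In the Alk4 line edgeR called 0 (55 to 428 at an unadjusted p under 0.05 per class; DESeq2 6), and in the difference 0 (132 to 316; DESeq2 2). In the Alk5 line it called 5: Gm10503 (log2 −8.02), the GLP-1 receptor gene Glp1r (−5.68) and Gm50240 (−2.44) in somatotropes, and Fshb in corticotropes (−2.55, adjusted p = 0.0456) and thyrotropes (−2.60, adjusted p = 0.0123). In both lines together it called Fshb in corticotropes (−2.21, adjusted p = 0.0235) and thyrotropes (−2.39, adjusted p = 0.000326). These genes were named after their values were seen, except Fshb. DESeq2 called 15 and 12. Lactotropes of the 3 female libraries lay mostly in a different cluster each (96.7%, 94.8% and 95.6% of those of Alk4 cKO 1, Alk4 cKO 3 and the control), so library and genotype are not separate there. Male somatotropes split too: Alk5 cKO 1 and the control (84.6% and 76.2%) shared 1 cluster, and Alk5 cKO 2 (87.1%) and 3 (94.2%) lay mostly in others. Fshb UMIs in the classes other than gonadotropes were 6.06 and 20.9 CPM (without TMM scaling) in Alk4 cKO 1 and 3 against 47.0 in the control, and 51.8, 50.6 and 40.4 in Alk5 cKO 1, 2 and 3 against 276. In the Alk5 control Fshb stood at 274 CPM in somatotropes, 293 in lactotropes, 254 in melanotropes and 312 in stem cells, against 3189 in gonadotropes. The Fshb calls in corticotropes and thyrotropes may therefore reflect background rather than a change in these cells.

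The share of nuclei that were gonadotropes was compared by library. It was 2.44% (exact 95% interval 2.17 to 2.74) and 3.20% (2.81 to 3.63) in Alk4 cKO 1 and 3 against 3.83% (3.46 to 4.24) in the control. In the Alk5 line it was 5.53% (4.95 to 6.16), 11.3% (10.6 to 12.0) and 6.95% (6.48 to 7.44) in cKO 1, 2 and 3 against 4.95% (4.61 to 5.31). The cKO mean was −1.01 percentage points from control in the Alk4 line and 2.96 in the Alk5 line (exact two-sided permutation within line, p = 0.667, smallest possible 0.0833). The test averages the differences of the lines, which were of opposite sign, and could not have reached 0.05, so it leaves open whether the share differed in either line. Counted among nuclei of named clusters only, the Alk4 difference was −0.0424 points and Alk4 cKO 1 lay above its control (4.42% against 3.85%). Without Alk5 cKO 2 the Alk5 difference was 1.28 points. Among nuclei with at least 1000 genes Alk5 cKO 1 lay below its control (5.63% against 7.20%). Shares depend on which nuclei were recovered, and the intervals cover counting error only.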

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

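The tests of the immediate early genes and of Gnrhr, and the test of depth, were chosen after the result was seen. The other tests of the genes that fell in the common effect were chosen before.

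In gonadotropes of both lines together 53 genes fell, and the hypothesis that signalling through ALK4 and ALK5 maintains them may be set against 3 technical explanations. A difference between whole libraries that is alike in both classes would move these genes in somatotropes too. But their median log2 fold change there was −0.124 (SD 0.374, 47 genes) against −1.49 in gonadotropes. Some are scarce in somatotropes (Cntn5 0.343 to 2.17 CPM, Nrp2 1.72 to 4.17), and all were chosen by their fall in gonadotropes. A library difference that acts on gonadotropes alone is not tested by this. Segments of strain genome around the Cre allele would place them on chromosome 5, which holds Gnrhr, but 5.66% of them lay there (3 of 53, exact 95% interval 1.18 to 15.7) against 6.57% of tested genes. Lower depth of the cKO sums would spare libraries as deep as their control. These genes cannot decide this, since they were called for being lower and lay below the control in every cKO library. Their median log2 difference was −1.44 in Alk4 cKO 1 (2291750 UMIs against 2243138 in the control) and −1.64 in Alk5 cKO 1 (1898020 against 1878116). It was −1.43, −1.69 and −1.81 in the shallower Alk4 cKO 3, Alk5 cKO 2 and Alk5 cKO 3. Cre itself, or the altered Gnrhr allele, cannot be told apart from loss of the receptor, because 0 libraries carry Cre without a floxed receptor. The 12 ways to choose 1 control library per line are too few for a share under 0.05: the real choice gave 73 genes and the highest other 20, so the real one alone of the 12 reached 73.

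Gnrhr differed between the lines by a log2 of 1.82 (Alk4 effect minus Alk5 effect, SE 0.43), with an adjusted p of 0.0118 over the always-named genes and 0.690 over all genes (edgeR), which marked it for a closer look as a difference between groups. Insertion of Cre at the Gnrhr locus, which both cKO lines carry, would lower it in both, but in the Alk4 line it stood at 1046 and 1162 CPM in cKO 1 and 3 against 804 in the control (log2 0.44, SE 0.31), against a log2 of −1.38 (SE 0.27) in the Alk5 line. This argues against an insertion effect alike in both lines as the whole cause only if the 1 Alk4 control was not low by chance. An effect of the insertion in males alone was not tested. A control library that was high by chance cannot be told apart from a change in Alk5 cKO: the control lay 6.46 SDs of the 3 cKO libraries above their mean, and there is 1 such control. In somatotropes of the Alk5 line Gnrhr had a log2 fold change of −1.86 (SE 0.66), no smaller than in gonadotropes. It stood there at 13.7 CPM in the control and 4.76, 4.81 and 1.79 in Alk5 cKO 1, 2 and 3, against 365 to 1305 in gonadotropes. Counts that low may be background, as for Fshb, so they cannot decide, and a difference of the whole library stays open. Line, sex, age and strain also stay open and were not tested.

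Immediate early genes differed between the 2 effects (camera adjusted p = 0.0134; adjusted p = 0.860 with an estimated correlation), and this is the third pattern weighed. A difference of the whole of Alk4 cKO library 1, for example in how the tissue was handled, may account for the Alk4 side of it: the list was raised by a log2 of 2.49 in gonadotropes of that library against the other female libraries and by a median of 2.02 in its 6 other tested classes. Genotype alone would raise the list in Alk4 cKO 3 too, but there it lay at −0.565 from the control. On the Alk5 side a difference of the whole control library cannot be told apart from genotype: the control lay above the mean of the cKO libraries by a log2 of 0.79 in gonadotropes and by a median of 0.593 in the 6 other classes, which went apart (2.01 in somatotropes, 1.03 in stem cells, 0.86 in thyrotropes, 0.32 in corticotropes, −0.01 in lactotropes and −0.22 in melanotropes). There the list had a median log2 of −0.60 in cKO gonadotropes with no member passing, and Egr1 had a log2 of −2.08 (SE 1.83). Without Alk4 cKO 1 and 3 in turn, which leaves no spread between females, the log2 of Egr1 was −2.06 and −2.07. What differed in Alk4 cKO 1 is not given in the sources used here.

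Also marked as differences between the 2 effects were GnRH signalling (camera adjusted p = 0.00767; adjusted p = 0.550 with an estimated correlation), which includes Gnrhr. Receptors and ligand traps had a camera adjusted p of 0.0208, and an adjusted p of 0.550 with an estimated correlation. Heat shock genes had a camera adjusted p of 0.0208, and an adjusted p of 0.550 with an estimated correlation. The gonadotrope share of nuclei was lower than control in both Alk4 cKO libraries and higher in all 3 Alk5 cKO libraries as reported, with a difference of −3.98 percentage points between the line differences, which was not tested. These directions depend on the nuclei counted: among nuclei of named clusters, a setting chosen after the data were seen, Alk4 cKO 1 was higher than control (4.42% against 3.85%), and among nuclei with at least 1000 genes Alk5 cKO 1 was lower (5.63% against 7.20%).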

How the results depend on the processing

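The settings without Alk4 cKO 1 and Alk5 cKO 2 together, with nuclei of named clusters only, and with clustering that left out the gonadotrope list and the called genes were chosen after the result was seen. The others were chosen before. Of the values for comparisons under an alternative, 87 stayed within 1.5 times or within the spread of the reported value and 71 did not. Of those for single genes, 4014 kept direction and side of the threshold, 172 no longer passed and 176 newly passed, and none that had been called turned in sign. Except where stated, the cause was not tested.

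Counts are given in the order Alk4 line, Alk5 line and both lines together (3, 109 and 73 as reported), then the difference (0, with 678 genes at an unadjusted p under 0.05) and the contrast between lines (454). With no filter on low counts, which adds genes both to the test and to the estimate of spread, they were 102, 485, 514, 101 and 1233. DESeq2 gave 9 in the Alk4 line, 152 in both lines together and 2 in the difference. A mean count of at least 50, which tests fewer genes, gave 14 in the Alk5 line, 23 in both and 225 between lines. With doublets kept they were 70 in the Alk5 line and 34 in both. Using only the libraries of the line gave 418 in the Alk5 line, and thinning to the smallest total gave 1 in the Alk4 line. Without both Alk4 cKO 1 and Alk5 cKO 2 they were 28, 298, 12 and 46.

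Relative to somatotropes the counts (1, 54 and 29 as reported) were 2, 13 and 6 with doublets kept. In the Alk4 line the count was 2 with at least 1000 genes per nucleus, with each library clustered alone, with clustering without the gonadotrope list, and with clustering without the list and the called genes. In both lines it was 44 with each library clustered alone. Without both Alk4 cKO 1 and Alk5 cKO 2 they were 86, 354 and 213. In the other classes DESeq2 called 6, 15 and 12 and, in the difference, 2, against 0, 5, 2 and 0 by edgeR (55 to 428 genes of a class at an unadjusted p under 0.05 in the Alk4 line). Lists called by camera, 1 in the Alk5 line, 3 in both and 4 in the difference, were 0, 0 and 0 with an estimated correlation, and 0, 0 and 0 by fry for 1 direction. The difference in gonadotrope share of the Alk4 line was −0.0424 points among nuclei of named clusters.

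Leaving out 1 library at a time gave 1 to 84 genes in the Alk4 line (84 without Alk4 cKO 3, 75 without Alk4 cKO 1, 1 without Alk5 cKO 2). It gave 13 to 423 in the Alk5 line (423 and 403 without Alk4 cKO 3 and 1; 16, 13 and 21 without Alk5 cKO 1, 2 and 3) and 3 to 314 in both (314 without Alk4 cKO 3; 22, 17 and 41 without Alk5 cKO 1, 2 and 3; 3 without the Alk5 control). It gave 0 to 125 in the difference (125 and 6 without Alk4 cKO 1 and 3) and 229 to 1012 between lines (916 and 1012 without Alk4 cKO 1 and 3; 282 and 229 without Alk5 cKO 1 and 2). Relative to somatotropes it gave 0 to 16 (9 and 16 without Alk4 cKO 1 and 3; 0 without Alk5 cKO 2), 2 to 200 (189 and 200 without Alk4 cKO 1 and 3; 23, 2 and 15 without Alk5 cKO 1, 2 and 3) and 5 to 222 (80 and 222 without Alk4 cKO 1 and 3; 5 without Alk5 cKO 2). The gonadotrope share difference ranged from −1.39 to −0.636 points in the Alk4 line and from 1.28 to 4.16 in the Alk5 line, and the Fshb share difference from −57.8 to −24.9 and from −57.4 to −41.9 points. A group with 1 library, as both controls are, is assumed to vary like the other groups. Without the control of a line the fit of both lines together takes its genotype term from the other line alone. Without Alk4 cKO 1 or 3 the Alk4 cKO group also has 1 library, so no spread between females enters the fit of group means.

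Fshb passed in both lines together with no filter on low counts (adjusted p = 5.68e-12) and under no other alternative, where adjusted p reached 1. Settings that keep all libraries ended calls of named genes in the Alk5 line (mean count at least 50: Gata2, Gnrhr, Itgbl1, Nek10, Pcdh15, Phex and Rftn1; doublets kept: Car10, Gnrhr, Itgbl1, Pcdh15 and Rftn1; thinned: Gnrhr and Nek10; at least 1000 genes: Phex and Ptprz1; no robust fit: Gnrhr; no gonadotrope list: Pcdh15). They did so in both lines together (mean count at least 50: Chl1, Hunk, Itgbl1, Nnat, Pitx1, Pld5 and Ptprz1; doublets kept: these without Chl1, and Elmo1 and Rftn1; thinned: Elmo1, Hunk, Itgbl1 and Pitx1; no robust fit: Hunk, Nnat and Pitx1; at least 1000 genes: Chl1 and Ptprz1; clustering: Chl1, Hunk and Pcdh15). The median log2 fold change of all genes was at most 0.0342 from 0 under TMM, RLE and DESeq2 scaling. Of the called genes, 25.7% were higher in the Alk5 line and 27.4% in both lines by edgeR with TMM, 25.5% and 28.6% with RLE, and 40.7% and 38.8% by DESeq2. In the Alk4 line 0 of 3 were higher by edgeR and 2 of 9 by DESeq2. In simulated data with the libraries of this design 4.62% of genes changed by 1 log2 unit were recovered in each line and 35.4% in both together, where more libraries are pooled. The simulated libraries were drawn at the totals of the real ones, and other depths were not simulated. Among the 12 choices of 1 control per line, others gave up to 7 genes in the Alk4 line (3 in the real choice), and in the Alk5 line 74 and 136 with the real Alk5 control (109 in the real choice) and 0 without it. No paired analysis was possible because replicate numbers follow only the order of the samples.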

Other observations

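No test of an explanation was run for the values in this part; the contrast between lines was chosen before the data were examined, and the cluster positions were noted after the data were seen.

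Between the lines (male Alk5 libraries minus female Alk4 libraries), gonadotropes differed in 454 genes, 186 higher and 268 lower in males (edgeR, 14349 genes; DESeq2 390). Chaperones and regulators of the endoplasmic reticulum, where hormones are folded, were higher in males: of 12 members 4 rose, Pdia6 (log2 1.22, adjusted p = 0.0140), Calr (1.19, adjusted p = 0.0327), Xbp1 (1.07, adjusted p = 0.0364) and Dnajb9 (0.94, adjusted p = 0.0306). Of them 9 passed when adjusted over the list alone (camera adjusted p = 2.24e-07; adjusted p = 0.325 with an estimated correlation; fry adjusted p = 0.128). Mitochondrial transcripts rose likewise, with 4 of 10 members passing, mt-Nd1 (1.59), mt-Nd2 (1.70), mt-Nd4 (1.60) and mt-Co1 (1.33), and 9 when adjusted over the list alone (camera adjusted p = 4.11e-11; adjusted p = 0.325 with an estimated correlation). This was not limited to gonadotropes: the median percent of mitochondrial UMIs over nuclei of all classes was 0.169, 0.0820, 0.259 and 0.208 in Alk5 cKO 1, 2 and 3 and the Alk5 control, and 0.109, 0.0507 and 0.0798 in Alk4 cKO 1 and 3 and the Alk4 control, so library quality stays open. Heat shock genes had no member passing and 5 of 6 when adjusted over the list alone (camera adjusted p = 0.000442; adjusted p = 0.325 with an estimated correlation). Pgr, the progesterone receptor gene, was lower in males (log2 −1.78, adjusted p = 0.000703), and with it the steroid receptor list (camera adjusted p = 0.0155; adjusted p = 0.325 with an estimated correlation).

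Other members of the fixed lists that differed between the lines included, lower in males, Foxp2 (log2 −1.37), Bmpr1b (−2.15), Sema3a (−2.81) and Unc5d (−1.45). Higher in males were the prohormone convertase gene Pcsk2 (1.69), the channel genes Cacna1e (2.93) and Kcnq3 (2.05) and the guidance receptor gene Dcc (1.49). The count was 916 and 1012 without Alk4 cKO 1 and 3, and 282 and 229 without Alk5 cKO 1 and 2. Single genes did not pass without 1 library: Calr (adjusted p = 0.115) and Pdia6 (0.0590) without Alk5 cKO 2, Xbp1 (0.0805 and 0.116) and Dnajb9 (0.0720 and 0.0996) without Alk5 cKO 1 and 2, Cacna1e without Alk5 cKO 3 (0.0532) and Kcnq3 without Alk4 cKO 1 (0.0596). Without Alk5 cKO 3, Prl (log2 −1.97), Pomc (1.21), Grem1, Hsp90aa1, Inhbb and Itpr3 passed (edgeR adjusted p 5.14e-05 to 0.0428). Without Alk4 cKO 1, which leaves 1 Alk4 cKO library, the log2 was −1.35 for Prl, −1.06 for Bmp6 and 1.18 for Cyp2f2. Without Alk4 cKO 3, likewise, it was −2.11 for Prl, −1.07 for Btg2 and 0.79 for Hspd1. Prl and Pomc are hormone transcripts of other pituitary cells and may be background here. Prl stood at 17097 to 46858 CPM in female and 5293 to 9915 in male gonadotropes. In melanotropes it stood at 21022 to 53194 and 4551 to 11904. Sex, line, age and strain go together in this contrast.

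Gonadotropes, somatotropes, lactotropes and melanotropes of the 2 lines lay mostly in separate clusters, whereas all corticotropes lay in 1 cluster and all thyrotropes in another. Of female gonadotropes, 91.9% to 96.2% per library lay in 1 cluster, and of male gonadotropes at least 99.7% in another. Lactotropes of the females split by library, with 96.7% of those of Alk4 cKO 1, 94.8% of those of Alk4 cKO 3 and 95.6% of those of the control each in a different cluster. Somatotropes of the males also split by library, with 84.6% of those of Alk5 cKO 1 and 76.2% of those of the control in 1 cluster, 87.1% of those of Alk5 cKO 2 in another and 94.2% of those of Alk5 cKO 3 in yet another.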
